A study of Homo sapiens with 9 samples.

How the data were processed

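The samples were 9 total RNA preparations of HepG2 cells, a line established from a human hepatocellular carcinoma, hybridized to Illumina HumanHT-12 v4 arrays. Samples were grouped by the culture format that the labels give: 3 of 2D culture, 3 of static 3D culture and 3 of perfused 3D culture. The array positions in the labels place 6 arrays on BeadChip 1 (replicates 1 and 2 of 2D and of static 3D, replicates 1 and 3 of perfused 3D) and 3 arrays on BeadChip 2 (1 of each format).

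Per the file headers, the deposited signal table holds for each of 47323 probes an average bead signal. It was taken as an intensity on a linear scale, neither background-subtracted nor normalized between arrays. Beside it, per the file headers, stands a detection p-value for each probe and array, which was taken to compare the probe with negative control beads. A further deposited table holds the authors' processed values on a log2 scale. The method behind them is not given in the sources used here. Within each array, 99.5% to 99.7% of those values lay within 0.01 log2 units of the log2 of a linear function of the signal (slope 0.891 to 1.18, offset -146 to -117). Their medians were 7.61, 7.60 and 7.66 in 2D replicates 1, 2 and 3, 7.56, 7.61 and 7.53 in static 3D, and 7.59, 7.60 and 7.56 in perfused 3D. The authors' values served as an alternative source. The scanner, its software and any earlier summarization are not given in the sources used here.

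The signals were background-corrected by the normexp method from the detection p-values, given an offset of 16, quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.05 on at least 3 of the 9 arrays were kept, which left 15302. Gene symbols were updated by Entrez Gene ID from a RefSeq table of assembly GRCh38.p14, used for names only: 35672 probes matched, 8790 symbols changed, and 8381 named probes without a match kept the symbol of the file. Chromosomes are those of the file. Of the passing probes, 14677 carried a symbol and 625 did not. For each gene the probe with the highest mean over the 9 arrays was tested, which gave 11915 genes. Of these genes, 2296 had more than 1 passing probe, and the report gives the other probe's change where it differed for a named gene.

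One linear model was fitted to each gene over all 9 arrays with limma's lmFit and eBayes (residual degrees of freedom 6, prior degrees of freedom 4.84), with no covariate. The 3 comparisons were static 3D against 2D, perfused 3D against 2D, and perfused 3D against static 3D. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison with a threshold of 0.05. Rose, fell, higher and lower refer to that threshold. Before the data were examined, 41 gene lists, the tests, the rule for named genes and most alternatives were fixed. The lists were tested with limma's camera at a preset correlation between genes of 0.01, for lists with at least 5 tested members, adjusted over the 40 lists that met this. Camera with an estimated correlation was an alternative, and fry, a rotation test of a list's own genes, and median scaling for lists were added after seeing the data.

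Named genes were, in each comparison, the 10 largest rises and the 10 largest falls among called genes with no overlap between the 3 arrays of each group, up to 4 called members of each list with the largest change, and 11 genes given whatever their values (ALB, AFP, HNF4A, CYP1A1, CYP3A4, CYP3A7, CA9, VEGFA, MKI67, GAPDH and 1 that is not reported here). CYP3A4, CYP3A7 and MKI67 were on the array but did not pass the detection filter. From the genes so named, the report prefers as examples those that stayed called with any 1 array left out. Values are log2 changes ± SE from the model with 3 arrays per group. For a gene not detected on any array of one group, the fold is given as "at least": that group's arrays were set to the lowest normalized intensity of any detected probe on the same array, or to the gene's own value if higher. After the data were seen, the same floor was applied to the undetected arrays of genes detected on only some arrays of the lower group, and those values are given beside or in place of the fold for the largest such changes.

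The similarity of the static and perfused changes was measured across genes, beside 100 simulations (seed 20) without change that share the 2D arrays. The same model and threshold were tested on simulated normalized values with 200 changed genes, spread over 3 sizes of change, per comparison. Values were drawn independently for each gene. Background correction, normalization, the detection filter and the choice of probe were not rerun, so the shares do not cover those steps. At a log2 change of 0.5 the model recovered 19.4% of the changed genes in static 3D against 2D and 20.9% in perfused 3D against 2D. In perfused against static 3D it recovered 17.9%. At a log2 change of 1 the shares were 94.0%, 91.0% and 94.0%, and at 2 they were 100% in each. Among unchanged genes, 0.0512%, 0.102% and 0.0768% were called.

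Alternatives were no background correction, an offset of 50, median scaling, the authors' values, no detection filter, detection p under 0.01 on all 9 arrays, all probes tested, an intensity trend with robust variance, array weights, only the 2 groups compared, BeadChip or replicate number (or both) as a block, each BeadChip alone, each array left out in turn, an adjusted p under 0.01 and a change of at least 2-fold. Replicate numbers did not pair the arrays: after removing group means, arrays of the same number correlated at -0.0871 to 0.146 and arrays of different numbers at -0.121 to 0.140. The 3 pairs with both arrays on BeadChip 2 correlated at 0.112 to 0.146, and the main model had no term for BeadChip. With BeadChip as a block, 827 genes were higher and 748 lower in static 3D and 508 and 564 in perfused 3D. Between perfused and static 3D they were 485 and 562. Probes without a symbol were tested but not named.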

Results

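Gene expression was measured in HepG2 cells, a human liver cancer line that keeps part of the secretory and metabolic program of hepatocytes, after 5 days in 3 culture formats. In 2D culture the cells grew as a monolayer. In static 3D culture they were seeded into a scaffold of microporous polycarbonate standing in a well, and in perfused 3D culture the same kind of scaffold sat in a bioreactor driven by a pump. Each format had 3 arrays, and 2D is the control. Seeding was with 250000 cells in 2D and 1000000 in both 3D formats, so the number of cells at the start went with 2D against 3D. The labels do not say that the arrays of a format came from separate cultures, and p-values then measure only the spread between these arrays, which may be technical.

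Per array, 12677 to 15199 of the 47323 probes were detected. The mean number of detected probes was 12973 ± 509 (SD, n = 3) in 2D, 14607 ± 730 in static 3D and 13920 ± 689 in perfused 3D. Across genes, which are not independent replicates, arrays correlated at r = 0.980 to 0.990 within formats and 0.964 to 0.983 between them. The first principal component held 29.8% of the variance and ran from 2D, through perfused, to static 3D. The second held 27.6% and set the perfused arrays apart from the other 6.

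The comparison of static 3D with 2D asks what growth in the scaffold does without perfusion. Among the largest rises were genes known to respond to low oxygen. ANKRD37 (Entrez Gene 353322, chromosome 4), a target of hypoxia-inducible factors, rose 6.71-fold (log2 change 2.75 ± 0.20, adjusted p = 0.000222), and HILPDA (Entrez Gene 29923, chromosome 7), which promotes storage of lipid in droplets, also rose 6.71-fold (2.75 ± 0.21, adjusted p = 0.000222). With undetected 2D arrays set to the detection floor, these rises were at least 6.41-fold and 5.33-fold. The histone gene H2BC5 rose about as much (2.73, at least 6.34-fold with the detection floor). Other large rises, as in EBI3 and PRSS8, were also outside the hypoxia-responsive list. Among the fixed lists, 10 of 40 plasma protein, 7 of 12 histone and 11 of 49 ribosomal protein genes rose. In turn, 12 of 38 DNA replication, 11 of 47 mitosis, 4 of 8 metallothionein and 6 of 30 cytoskeletal genes fell. Camera called these 7 lists, with an adjusted p = 0.0558 to adjusted p = 0.441 with an estimated correlation. Of 11915 genes tested, 823 were higher and 759 lower. With median scaling in place of quantile normalization, which moved the median change of all genes from -0.02 to 0.17, the split was 1743 higher and 159 lower, and with the authors' values it was 1842 and 365.

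Among 36 tested hypoxia-responsive genes, 13 rose and 1 fell (18 and 1 adjusted over the list alone), with a median change of 0.53. The list was called higher (camera, adjusted p = 9.75e-09, and adjusted p = 0.364 with an estimated correlation), and 8 to 17 members rose with any 1 array left out. EGLN3, an oxygen-sensing prolyl hydroxylase, rose at least 1.26-fold (adjusted p = 0.00546). VEGFA, the main angiogenic growth factor, rose by 1.09 ± 0.25 (adjusted p = 0.0192), a call that was lost without 2D replicate 2 or 3 or static replicate 1 or 3 (adjusted p from 0.00146 to 0.0615 over the 9 arrays left out in turn). CA9, a carbonic anhydrase induced by low oxygen, changed by 0.63 ± 0.23 and was not called (adjusted p = 0.0970), except without perfused replicate 3 (adjusted p = 0.0116 there, the lowest of a range up to 0.238).

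Secreted plasma proteins rose in 10 of 40 members with 0 falling (10 and 0 adjusted over the list alone), with a median of 0.26 (adjusted p = 0.000487, and adjusted p = 0.377 with an estimated correlation). Their examples were AMBP, the precursor of alpha-1-microglobulin and bikunin, at 1.16 ± 0.17 and F5, coagulation factor V, at 1.05 ± 0.13. Acute phase and complement genes rose in 7 of 21 and fell in 1 (10 and 1 adjusted over the list alone; median 0.38, adjusted p = 0.00333, and adjusted p = 0.303 with an estimated correlation). C4BPA, an inhibitor of the classical complement pathway, rose 3.51-fold (1.81 ± 0.17, at least 3.07-fold with the detection floor), and SAA4, a constitutive serum amyloid A, fell by 1.05 ± 0.15. ALB and AFP, the main plasma proteins of adult and fetal liver, changed by -0.10 ± 0.11 and 0.08 ± 0.11 and were not called; both lay at 15.3 to 15.6 log2 units in every format, near the top of the range. With 1 array left out, 6 to 15 plasma protein genes and 3 to 10 acute phase genes rose.

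Of 16 genes of gluconeogenesis and glycogen, 6 rose and 0 fell (6 and 0 adjusted over the list alone; 0.17, adjusted p = 0.00945, and adjusted p = 0.364 with an estimated correlation). Among them were PPP1R3C, a glycogen-targeting subunit of protein phosphatase 1, at 3.18-fold (1.67 ± 0.16) and GBE1, the glycogen branching enzyme, at 0.82 ± 0.16. Cholesterol synthesis and uptake genes rose in 5 of 23 (8 adjusted over the list alone; 0.30, adjusted p = 0.00551, and adjusted p = 0.459 with an estimated correlation). But 0 rose without 2D replicate 2, 2D replicate 3 or static replicate 3. Genes of fatty acid and triglyceride synthesis rose in 4 of 25 (5 adjusted over the list alone; 0.20, adjusted p = 0.0328, and adjusted p = 0.364 with an estimated correlation). The call was lost without 2D replicate 2 or static replicate 3 (adjusted p from 0.0196 to 0.0716 over the 9 arrays left out in turn). Lysosomal genes rose in 7 of 33 and fell in 2 (11 and 4 adjusted over the list alone; 0.17, adjusted p = 0.0328, and adjusted p = 0.314 with an estimated correlation). LAMP2, a lysosomal membrane protein, rose by 1.08 ± 0.13 and TPP1, a lysosomal peptidase, by 0.98 ± 0.11. That list call was lost without 2D replicate 1 or 2 or static replicate 3 (adjusted p from 0.0290 to 0.0704 over the arrays left out) and with replicate number as a block (adjusted p = 0.0572). With 1 array left out, 3 to 6 gluconeogenesis, 0 to 9 cholesterol, 0 to 7 fatty acid and 3 to 8 lysosomal genes rose.

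The growth factor list rose in 6 of 19 members (7 rose and 4 fell adjusted over the list alone; 0.12, adjusted p = 0.0469, and adjusted p = 0.377 with an estimated correlation). Examples were IRS1, the adaptor of the insulin receptor, at least 2.12-fold higher and EGFR at 1.09 ± 0.19. This call was lost without 2D replicate 1 or 2 or static replicate 2 or 3 (adjusted p from 0.0178 to 0.106 over the arrays left out) and with BeadChip as a block (adjusted p = 0.0550). Oncofetal and progenitor genes rose in 5 of 19 and fell in 1 (8 and 1 adjusted over the list alone; 0.22, adjusted p = 0.0328, and adjusted p = 0.303 with an estimated correlation). Examples were GPC3, an oncofetal glypican, at 0.71 ± 0.13 and the progenitor factor SOX9 at 0.71 ± 0.12. The oncofetal call was lost without 2D replicate 2 or static replicate 2 (adjusted p from 0.0199 to 0.0912). Ribosomal protein genes rose in 11 of 49 (22 adjusted over the list alone; 0.33, adjusted p = 5.88e-07, and adjusted p = 0.0558 with an estimated correlation). Among them were RPL15 at 0.93 ± 0.13 and RPL22 at 0.87 ± 0.14. Replication-dependent histone genes, whose copies share much of their sequence, rose in 7 of 12 (7 adjusted over the list alone; 1.01, adjusted p = 0.000425, and adjusted p = 0.303 with an estimated correlation). Examples were H2BC5 at 6.64-fold (2.73 ± 0.34, at least 6.34-fold with the detection floor) and H2AC18 at 1.37 ± 0.18. EBI3, a subunit of the cytokines IL-27 and IL-35, rose at least 3.85-fold, and PRSS8, an epithelial membrane protease, at least 3.38-fold. Leaving out any 1 array, 3 to 6 growth factor, 2 to 7 oncofetal and 7 to 18 ribosomal protein genes rose.

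DNA replication and G1/S genes fell in 12 of 38 and rose in 0 (13 and 0 adjusted over the list alone), with a median of -0.30 (adjusted p = 0.000105, and adjusted p = 0.441 with an estimated correlation). G2/M and mitosis genes fell in 11 of 47 and rose in 0 (11 and 0 adjusted over the list alone; -0.22, adjusted p = 0.000487, and adjusted p = 0.364 with an estimated correlation). HJURP, the chaperone of the centromeric histone CENPA, fell by 1.06 ± 0.13. Under median scaling 0 of the replication genes fell, 1 rose, and 1 of the mitosis genes fell. The list medians there were -0.085 and -0.029, or -0.25 and -0.20 relative to the median of all genes. Without 1 array, 1 to 16 replication genes and 5 to 11 mitosis genes fell.

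Metallothionein genes, which encode near-identical metal-binding proteins, fell in 4 of 8 (6 adjusted over the list alone; -0.68, adjusted p = 0.000425, and adjusted p = 0.364 with an estimated correlation). Examples were MT1G at -0.97 ± 0.15 and MT1E at -0.89 ± 0.13. NRF2 targets fell in 5 of 24 (7 adjusted over the list alone; -0.24, adjusted p = 0.00666, and adjusted p = 0.377 with an estimated correlation). An example was the aldo-keto reductase AKR1B10 at -0.99 ± 0.19, though under median scaling the list median was 0.002, or -0.17 relative to all genes. YAP and SRF targets fell in 6 of 21 (6 adjusted over the list alone; -0.22, adjusted p = 0.0254, and adjusted p = 0.303 with an estimated correlation). But under median scaling 4 fell and 3 rose with a median of 0.04, or -0.13 relative to all genes, and the call was lost without 2D replicate 2 (adjusted p from 0.0143 to 0.0509 over the arrays left out). TAGLN, an actin-binding protein of contractile cells, fell by 1.52 ± 0.22 and MYL9, a myosin light chain, by 1.18 ± 0.14. Cytoskeletal genes fell in 6 of 30 and rose in 1 (7 and 1 adjusted over the list alone; -0.16, adjusted p = 0.0155, and adjusted p = 0.328 with an estimated correlation). An example was the epithelial keratin KRT8 at -0.91 ± 0.15, and the list median turned to 0.03 under median scaling, or -0.14 relative to all genes. NF-kappaB and chemokine genes fell in 2 of 16 (3 adjusted over the list alone; -0.26, adjusted p = 0.0328, and adjusted p = 0.314 with an estimated correlation). The call was lost without 2D replicate 2 or static replicate 2 (adjusted p from 0.0133 to 0.0912). GATA2, a transcription factor of blood and endothelial development, was at least 3.10-fold lower, and FOSL1, an AP-1 subunit, fell by 1.45 ± 0.27. Leaving out any 1 array, 2 to 5 metallothionein, 3 to 7 NRF2, 3 to 8 cytoskeletal and 1 to 3 NF-kappaB genes fell.

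The gene counts were lower without any single 2D or static array. Fewer arrays also lower the power to call genes, and the cause was not tested. Without 2D replicate 1, 2 or 3, the counts were 407 and 327, 563 and 518, and 423 and 374 (higher and lower). Without static replicate 1, 2 or 3, they were 341 and 285, 575 and 497, and 447 and 456. Within BeadChip 1, with 2 arrays per format, they were 46 and 13.

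**Figure D1:**
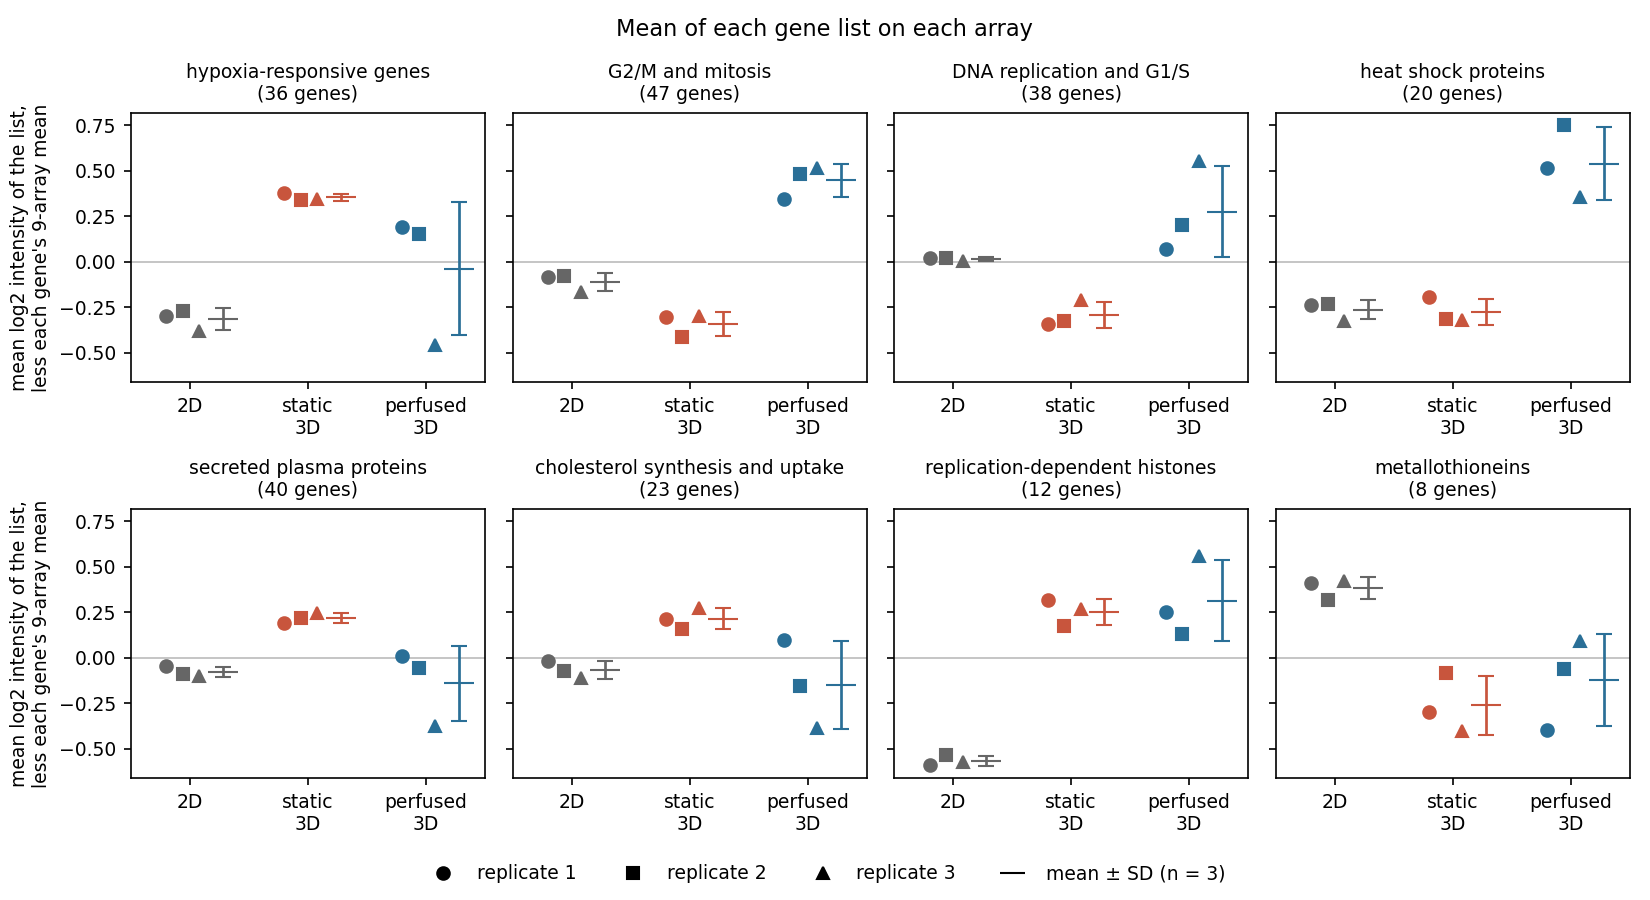
Mean log2 intensity of 8 gene lists on each of the 9 arrays, less each gene's mean over the 9 arrays (vertical axis, log2 units); symbols are replicates, and bars are the mean ± SD of 3 arrays. The hypoxia-responsive list lay at 0.34 to 0.38 on the static arrays and at 0.19, 0.15 and -0.46 on perfused replicates 1, 2 and 3, while the heat shock list lay at 0.36 to 0.75 on the perfused arrays and no higher than -0.19 elsewhere.

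Perfused 3D against 2D asks what the scaffold and perfusion do together. Heat shock genes stood at the top: HSPA6 (Entrez Gene 3310, chromosome 1), a strictly inducible HSP70, rose 9.15-fold (3.19 ± 0.30, adjusted p = 0.000416, 1.59 by another probe) and HSPA1B (Entrez Gene 3304, chromosome 6) 8.10-fold (3.02 ± 0.26, adjusted p = 0.000309). HILPDA and ANKRD37 rose 6.51-fold and 5.90-fold, or at least 5.17-fold and 5.64-fold with the detection floor. Among the fixed lists, 20 of 47 mitosis and 7 of 12 histone genes rose, 5 of 20 immediate early genes rose and 2 fell, 7 of 21 YAP and SRF targets fell and 1 rose, and 4 of 8 metallothionein genes fell. Camera called these 5 lists, with an adjusted p = 0.162 to adjusted p = 0.552 with an estimated correlation. In all, 554 genes were higher and 622 lower. Under median scaling, which put the median change of all genes at 0.14, 1008 were higher and 177 lower, and with the authors' values 1197 and 365.

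Of 20 heat shock genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with a median of 0.46 (adjusted p = 2.19e-08, and adjusted p = 0.162 with an estimated correlation), and 5 to 9 rose with 1 array left out. HSPH1, a nucleotide exchange factor of HSP70, rose 3.75-fold (1.91 ± 0.20) and CACYBP, which binds calcyclin, 3.13-fold (1.65 ± 0.20). HSPA1A rose 5.08-fold (2.35 ± 0.32), but HSPA1A and HSPA1B are near-identical copies and their probes may not tell them apart. Immediate early genes rose in 5 of 20 and fell in 2 (7 and 2 adjusted over the list alone; 0.30, adjusted p = 0.0104, and adjusted p = 0.552 with an estimated correlation). Examples were IER5 at 1.62 ± 0.17, the mRNA decay factor ZFP36 at 1.61 ± 0.20 and the AP-1 subunit JUN at 1.39 ± 0.24. With 1 array left out, 3 to 6 immediate early genes rose and 0 to 2 fell.

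G2/M and mitosis genes rose in 20 of 47 and fell in 0 (33 and 0 adjusted over the list alone), with a median of 0.50 (adjusted p = 1.76e-15, and adjusted p = 0.162 with an estimated correlation); 9 to 21 rose with 1 array left out. BUB1, a kinase of the spindle checkpoint, was at least 2.56-fold higher, RACGAP1, which organizes the central spindle, at least 1.95-fold, and CENPA at least 1.88-fold. DNA replication genes rose in 5 of 38 and fell in 1 (8 and 1 adjusted over the list alone; 0.30, adjusted p = 0.00152, and adjusted p = 0.739 with an estimated correlation). An example was POLA2, a subunit of DNA polymerase alpha, at 1.00 ± 0.20. Perfused replicate 3 carried that call: its list mean was 0.55 against 0.07 and 0.20 in the other perfused arrays, and without it 1 rose, 2 fell and the adjusted p was 0.192, the highest of a range from 4.67e-06. Histone genes rose in 7 of 12 (7 adjusted over the list alone; 0.93, adjusted p = 1.93e-06, and adjusted p = 0.162 with an estimated correlation). Examples were H2BC12 at least 1.82-fold and H2AC18 at 1.48 ± 0.18. Ribosomal protein genes rose in 3 of 49 (2 adjusted over the list alone; 0.18, adjusted p = 0.00349, and adjusted p = 0.162 with an estimated correlation), led by RPL29 at 0.76 ± 0.13, and this call ended under median scaling (adjusted p = 0.0866). Leaving out any 1 array, 1 to 6 replication and 1 to 3 ribosomal protein genes rose.

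The hypoxia-responsive list was not called (8 of 36 rose and 1 fell; 8 and 4 adjusted over the list alone; median 0.09, adjusted p = 0.114), but perfused replicate 3 lay apart in it, with a list mean of -0.46 against 0.19 and 0.15. Without that array 11 rose, 1 fell, the median was 0.26 and the adjusted p was 9.71e-05. VEGFA changed by 0.17 ± 0.25 (adjusted p = 0.704) and by 0.54 without that array (adjusted p = 0.0455, in a range up to 0.942), and CA9 by -0.45 ± 0.23 (adjusted p = 0.244). DDIT4, a stress-induced inhibitor of mTORC1, rose 3.78-fold (1.92 ± 0.19).

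Acute phase and complement genes rose in 3 of 21 (3 adjusted over the list alone; 0.24, adjusted p = 0.0104, and adjusted p = 0.273 with an estimated correlation). Examples were C4BPA at 1.27 ± 0.17 and haptoglobin, HP, at 0.96 ± 0.15. The list of plasma proteins was not called (5 of 40 rose and 3 fell, adjusted p = 0.80), and ALB and AFP changed by -0.11 ± 0.11 and 0.09 ± 0.11, not called. Hepatocyte transcription factors as a list were not called either (3 of 22 rose and 4 fell, adjusted p = 0.987), yet NR0B2, the repressor SHP of bile acid signalling, rose 3.33-fold (1.74 ± 0.15) and NR1H4, the bile acid receptor FXR, rose by 1.00 ± 0.14, while HNF4A changed by 0.15 ± 0.15. CYP1A1, a target of the aryl hydrocarbon receptor, fell by 1.10 ± 0.25 (adjusted p = 0.0231). That call was lost without 2D replicate 3 or perfused replicate 1 or 2 (adjusted p from 0.00449 to 0.0792 over the arrays left out).

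YAP and SRF targets fell in 7 of 21 and rose in 1 (8 and 2 adjusted over the list alone; -0.32, adjusted p = 0.0103, and adjusted p = 0.162 with an estimated correlation). Examples were TAGLN at -1.23 ± 0.22 and the calponin CNN2 at -0.77 ± 0.12; under median scaling 4 fell and 2 rose. Metallothioneins fell in 4 of 8 (6 adjusted over the list alone; -0.54, adjusted p = 0.00651, and adjusted p = 0.552 with an estimated correlation). But 0 fell without any 2D array or perfused replicate 1. The ATF4 list fell in 6 of 26 and rose in 3 (8 and 3 adjusted over the list alone; -0.17, adjusted p = 0.0219, and adjusted p = 0.461 with an estimated correlation). Examples were ATF4 itself at -0.89 ± 0.15, although another ATF4 probe changed by -0.04, and SESN2, a sestrin, at -0.95 ± 0.14. Its median turned to 0.04 under median scaling, or -0.10 relative to all genes, where the call ended (adjusted p = 0.141), as it did with the authors' values (adjusted p = 0.130) and without 2D replicate 2 or perfused replicate 1 or 3 (adjusted p from 0.0133 to 0.0588). The largest falls were in MIR22HG, the host transcript of microRNA 22, at least 3.32-fold, and SNORA12, a small nucleolar RNA, by 2.05 ± 0.16. HERPUD1, an endoplasmic reticulum stress gene, fell by 1.04 ± 0.11.

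Without 2D replicate 1, 2 or 3 or perfused replicate 2, the gene counts dropped to 220 and 211, 297 and 324, 213 and 248, and 239 and 278 (higher and lower). They were 24 and 15 within BeadChip 1, and 339 and 369 when only these formats were fitted.

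**Figure D2:**
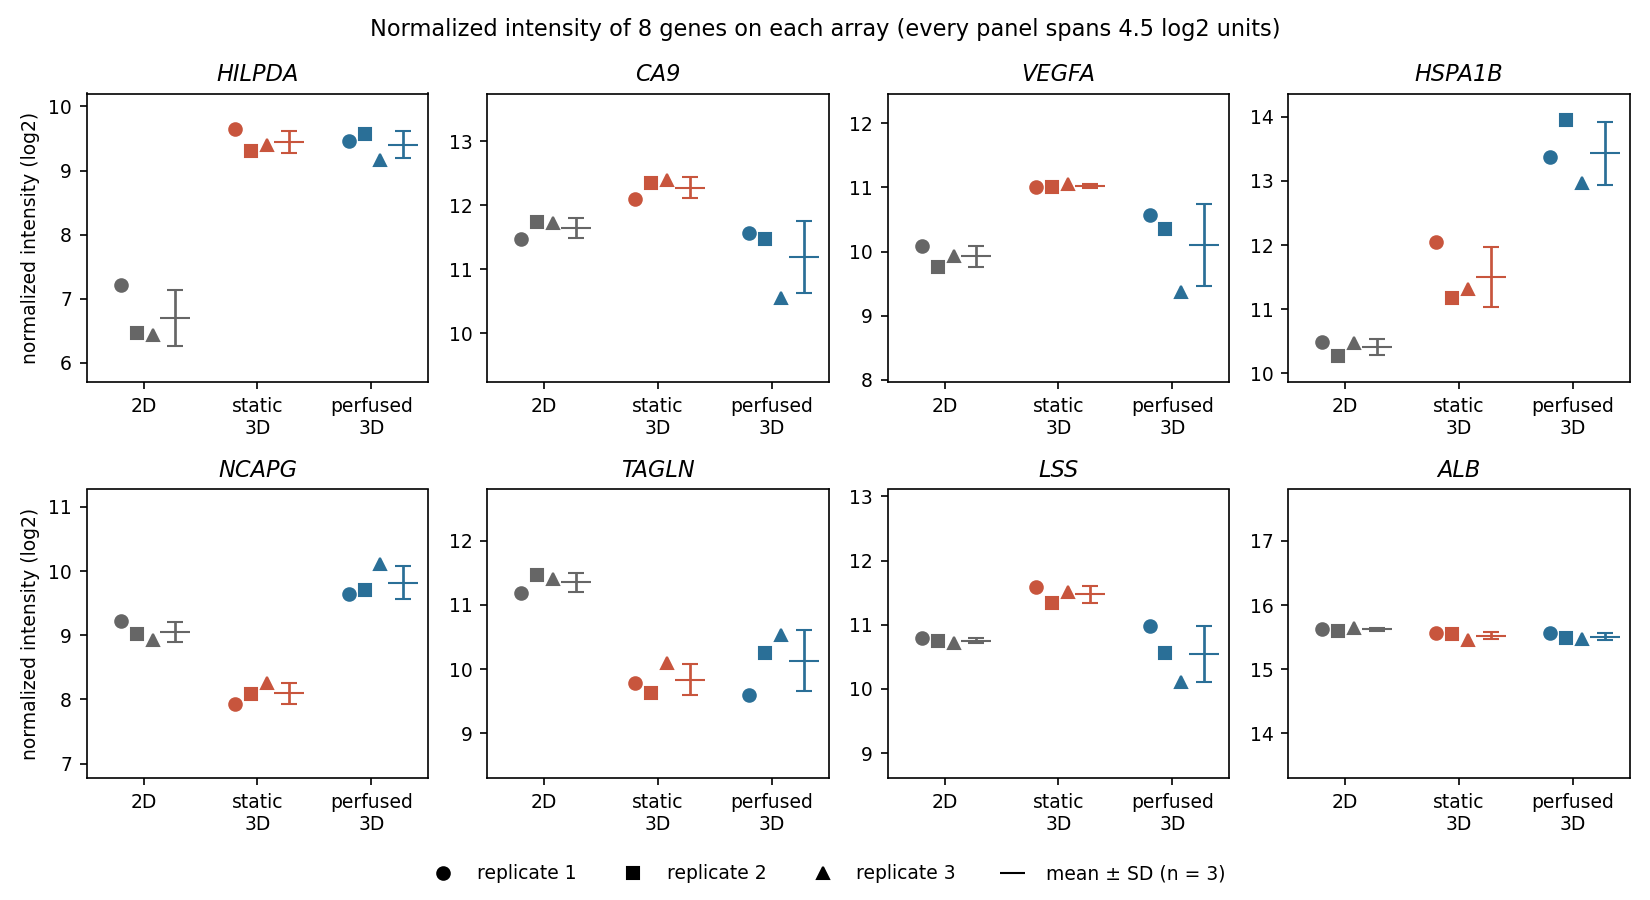
Normalized log2 intensity of 8 genes on each of the 9 arrays (vertical axis, log2 units, the same span in every panel); symbols are replicates and bars the mean ± SD of 3 arrays. HILPDA rose alike in both 3D formats, HSPA1B lay highest in perfused 3D, VEGFA was highest in static 3D with perfused replicate 3 below the other perfused arrays, and ALB changed by -0.10 and -0.11 against 2D.

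Perfused against static 3D compares scaffolds seeded with the same number of cells, with and without perfusion. With perfusion 36 of 47 mitosis, 19 of 38 DNA replication and 13 of 20 heat shock genes rose, while 10 of 40 plasma protein and 5 of 23 cholesterol genes fell, and 10 of 36 hypoxia-responsive genes fell and 3 rose. Camera called these 6 lists, with an adjusted p = 0.0822 to adjusted p = 0.484 with an estimated correlation. NCAPG (Entrez Gene 64151, chromosome 4), a subunit of the condensin that compacts mitotic chromosomes, rose 3.31-fold (1.73 ± 0.16, adjusted p = 0.000957), and EBI3 (Entrez Gene 10148, chromosome 19) was at least 3.69-fold lower (adjusted p = 0.00264), being detected on 1 of 3 perfused arrays. In all, 508 genes were higher and 575 lower. Median scaling gave 301 and 579, and the authors' values 511 and 874.

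G2/M and mitosis genes rose in 36 of 47 and fell in 0 (42 and 0 adjusted over the list alone), with a median of 0.81 (adjusted p = 5.3e-28, and adjusted p = 0.0822 with an estimated correlation), and with any 1 array left out 25 to 36 rose. Examples were BUB1 at 1.43 ± 0.21, the mitotic kinesin KIF20A at 1.39 ± 0.13 and the kinase AURKA at 1.29 ± 0.12. DNA replication and G1/S genes rose in 19 of 38 and fell in 0 (25 and 0 adjusted over the list alone; 0.57, adjusted p = 2.14e-14, and adjusted p = 0.429 with an estimated correlation). Examples were thymidine kinase, TK1, at 1.23 ± 0.20 and GINS2, of the replicative helicase, at 0.90 ± 0.13. Without perfused replicate 3, 29 mitosis and 11 replication genes rose, and 7 to 19 replication genes rose over all arrays left out in turn. Heat shock genes rose in 13 of 20 and fell in 0 (16 and 0 adjusted over the list alone; 0.76, adjusted p = 7.88e-13, and adjusted p = 0.142 with an estimated correlation). Examples were HSPA1B at 1.92 ± 0.26 and HSPH1 at 1.70 ± 0.20. HSPA6, which is not a member of the list, changed by 1.88 ± 0.30. Immediate early genes rose in 5 of 20 (6 rose and 1 fell adjusted over the list alone; 0.24, adjusted p = 0.0139, and adjusted p = 0.433 with an estimated correlation). Examples were the ERK phosphatase DUSP5 at 1.53 ± 0.25 and IER5 at 1.18 ± 0.17. The list call was lost without static replicate 2 (adjusted p = 0.143, in a range from 0.00178). NRF2 targets rose in 6 of 24 and fell in 1 (9 and 2 adjusted over the list alone; 0.22, adjusted p = 0.00931, and adjusted p = 0.433 with an estimated correlation). An example was the glutathione peroxidase GPX2 at 1.04 ± 0.19. That call was lost without perfused replicate 3 (adjusted p = 0.0802, in a range from 0.00154), and 2 to 7 members rose with 1 array left out.

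The hypoxia-responsive list fell in 10 of 36 and rose in 3 (15 and 3 adjusted over the list alone), with a median of -0.45 (adjusted p = 0.000206, and adjusted p = 0.484 with an estimated correlation). Without perfused replicate 3, 9 fell, 4 rose and the median was -0.25, and 4 to 14 fell over all arrays left out in turn. EGLN3 was at least 1.34-fold lower. CA9 fell by 1.08 ± 0.23 (adjusted p = 0.0189), lost without static replicate 2 or 3 (adjusted p from 0.0127 to 0.0631), and VEGFA by 0.92 ± 0.25 (adjusted p = 0.0458), lost without any 2D or static array or perfused replicate 2 (adjusted p from 0.0181 to 0.114). IGFBP3, a binding protein of insulin-like growth factors, fell by 2.08 ± 0.45. That call was lost without any 1 static array (adjusted p from 0.00415 to 0.0604). HILPDA and ANKRD37 differed by less than their spread, with -0.04 ± 0.21 and -0.19 ± 0.20.

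Plasma protein genes fell in 10 of 40 and rose in 0 (12 and 0 adjusted over the list alone; -0.22, adjusted p = 1.12e-05, and adjusted p = 0.429 with an estimated correlation). Examples were vitronectin, VTN, at -0.91 ± 0.16 and kininogen, KNG1, at -1.28 ± 0.25; 2 to 11 fell with 1 array left out, and 8 without perfused replicate 3. Cholesterol synthesis and uptake genes fell in 5 of 23 and rose in 0 (6 and 0 adjusted over the list alone; -0.27, adjusted p = 0.000104, and adjusted p = 0.429 with an estimated correlation). But 0 fell without static replicate 1 or perfused replicate 2. LSS, which closes the sterol rings, fell by 0.93 ± 0.19, lost without those same arrays (adjusted p from 0.00411 to 0.0576). The growth factor list fell in 5 of 19 (7 fell and 1 rose adjusted over the list alone; -0.18, adjusted p = 0.0138, and adjusted p = 0.429 with an estimated correlation). But 0 fell without any 1 static array. Genes of gluconeogenesis and glycogen fell in 2 of 16 (7 fell and 1 rose adjusted over the list alone; -0.16, adjusted p = 0.0303, and adjusted p = 0.429 with an estimated correlation). An example was GBE1 at -0.95 ± 0.16. The list call was lost without static replicate 1 or perfused replicate 3 (adjusted p from 0.0112 to 0.0814), and 1 to 5 members fell with 1 array left out. Glycolysis was called lower (-0.19, adjusted p = 0.0362, and adjusted p = 0.504 with an estimated correlation) although 0 of its 22 members passed, also adjusted over the list alone, and the call was lost without static replicate 1 or 3 or perfused replicate 3 (adjusted p from 0.0061 to 0.278).

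Amino acid degradation genes fell in 5 of 36 and rose in 2 (8 and 2 adjusted over the list alone; -0.15, adjusted p = 0.0362, and adjusted p = 0.451 with an estimated correlation). Examples were HAL, which deaminates histidine, at -1.31 ± 0.15 and BHMT, which remethylates homocysteine, at -1.25 ± 0.20. That list call was lost without static replicate 1 or 3 or perfused replicate 3 (adjusted p from 0.00625 to 0.237) and with replicate number as a block (adjusted p = 0.0561). The ATF4 list fell in 6 of 26 and rose in 1 (10 and 3 adjusted over the list alone; -0.22, adjusted p = 0.0138, and adjusted p = 0.429 with an estimated correlation). Examples were asparagine synthetase, ASNS, at -0.89 ± 0.12 and SESN2 at -0.82 ± 0.14 against DDIT4 at 0.99 ± 0.19. Ribosomal protein genes fell in 3 of 49 and rose in 1 (3 and 1 adjusted over the list alone; -0.12, adjusted p = 0.0114, and adjusted p = 0.291 with an estimated correlation). Examples were RPL15 at -0.76 ± 0.13 and RPL29 at 0.81 ± 0.13. Leaving out any 1 array, 3 to 7 amino acid and 1 to 4 ribosomal protein genes fell. Among single genes, BIRC7, an inhibitor of apoptosis, fell at least 4.12-fold (-0.86 log2 units by another probe), and MFNG, a glycosyltransferase of Notch receptors, at least 3.37-fold, each being detected on 1 of 3 perfused arrays. The matrix metalloproteinase MMP11 fell by 1.75 ± 0.16. CDH1, E-cadherin, fell by 1.11 ± 0.14. Without static replicate 1 or 2 or perfused replicate 2, the gene counts were 226 and 272, 233 and 291, and 180 and 245 (higher and lower). Without static replicate 3 they were 526 in all, 251 of them lower. Within BeadChip 1 no gene passed with limma at 2 arrays per format.

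**Figure D3:**
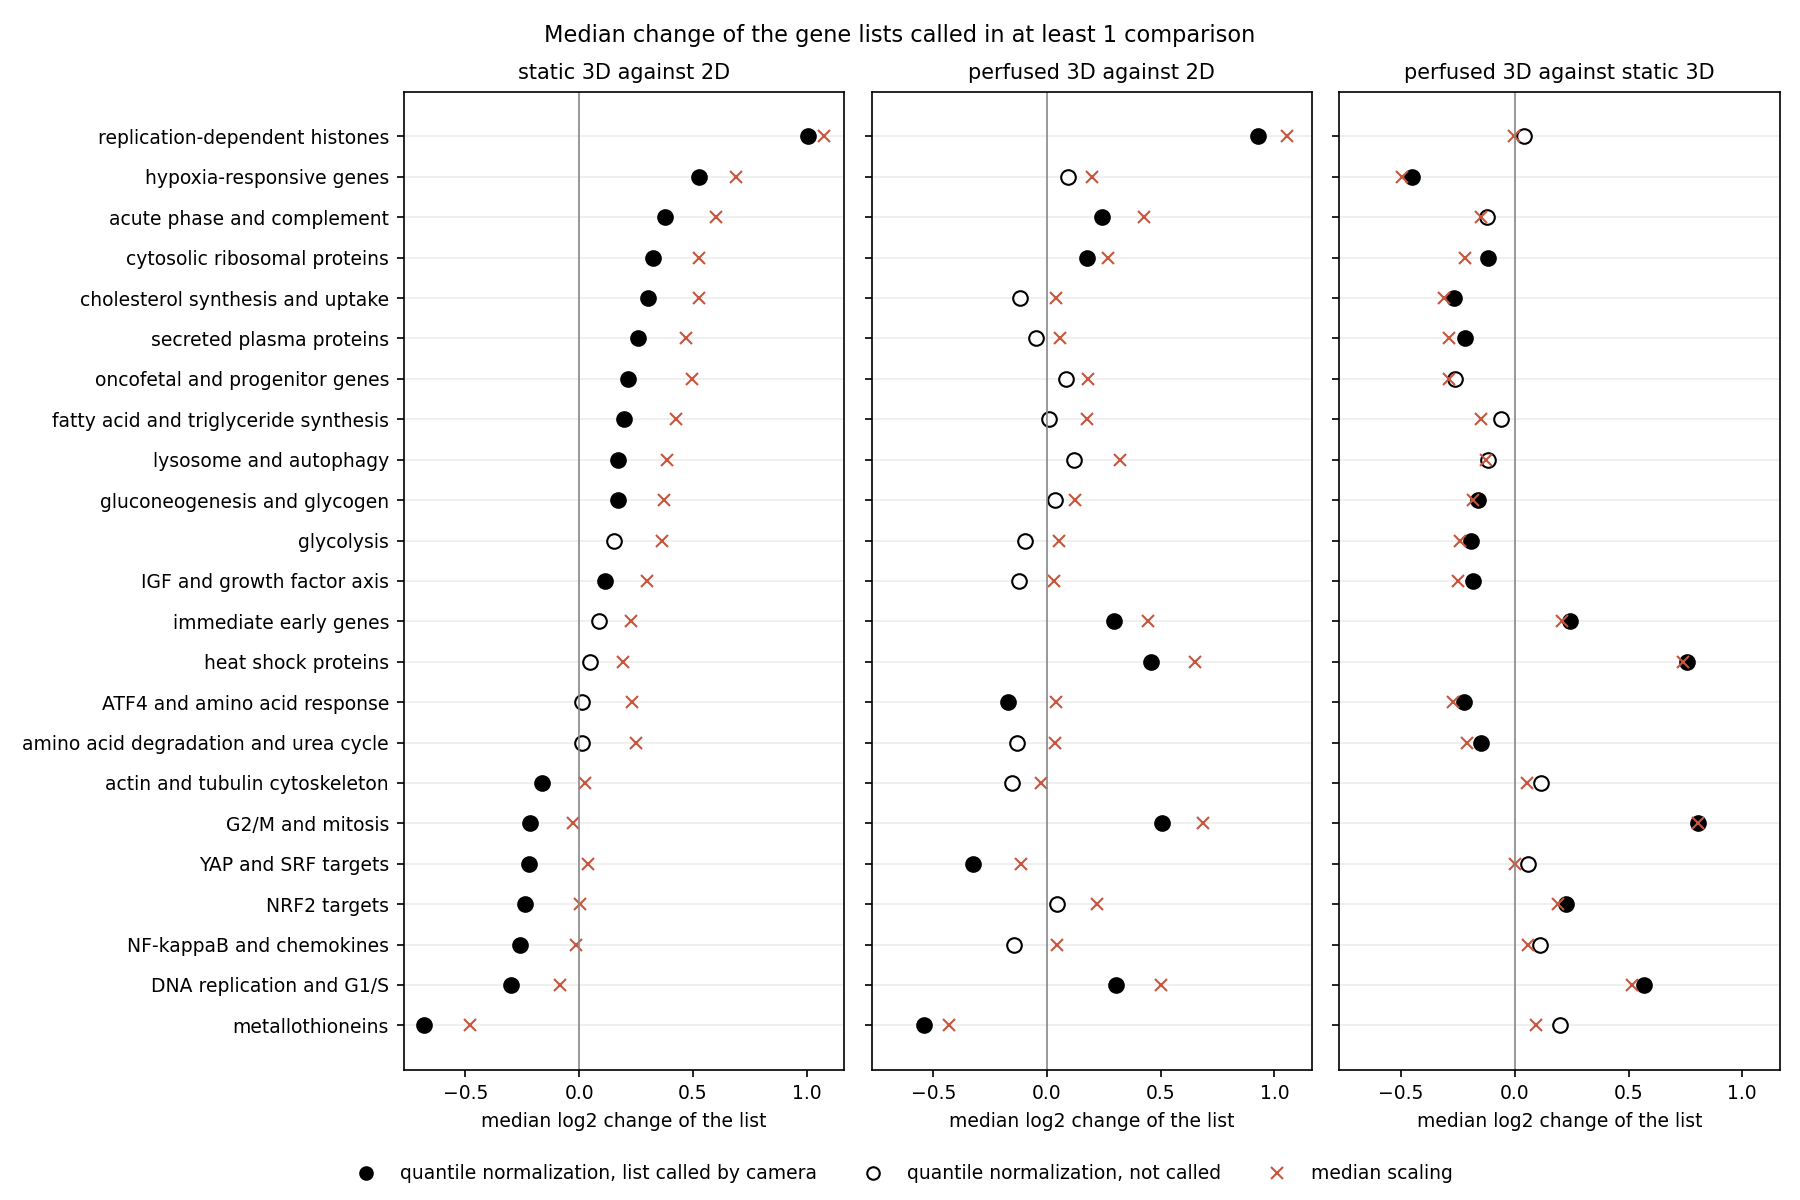
Median log2 change (horizontal axes) of the 23 gene lists called in at least 1 comparison, for each of the 3 comparisons; circles are quantile-normalized values, filled where camera called the list, and crosses are median scaling. The median of the mitosis list was -0.22 in static 3D, where 11 of 47 fell (adjusted p = 0.364 with an estimated correlation), and 0.50 in perfused 3D, where 20 of 47 rose (adjusted p = 0.162 with an estimated correlation). The medians of NRF2, cytoskeletal and YAP and SRF genes in static 3D, and of the ATF4 list in perfused 3D, were below 0 under quantile normalization and above 0 under median scaling. In perfused 3D against 2D the plasma protein, cholesterol, glycolysis, amino acid degradation, NF-kappaB and growth factor medians, not called there, turned in the same way.

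The changes against 2D in static and perfused 3D correlated across 11915 genes at r = 0.536. As both share the 2D arrays, simulated groups without change gave 0.499 on average and at most 0.517. The covariance was 0.0732 against 0.0151 in the simulations. With 1 array left out the correlation was 0.452 to 0.593, lowest without perfused replicate 1. No simulation was run with an array left out, and the value expected without change shifts with the number of arrays per group. That range therefore cannot be set against the simulated values. The simulations also drew genes independently, so they do not give the spread that correlated genes would have. Of the called genes, 214 were higher in both formats, 221 were lower in both, and 3 and 4 were called in opposite directions. The shared 2D arrays alone favour the same direction, and the overlap without any change was not computed. Of the 823 genes higher in static 3D, 228 were lower in perfused than in static 3D, and of the 759 lower ones 190 were higher, though these comparisons share the static arrays and such overlap arises in part without any change.

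**Figure D4:**
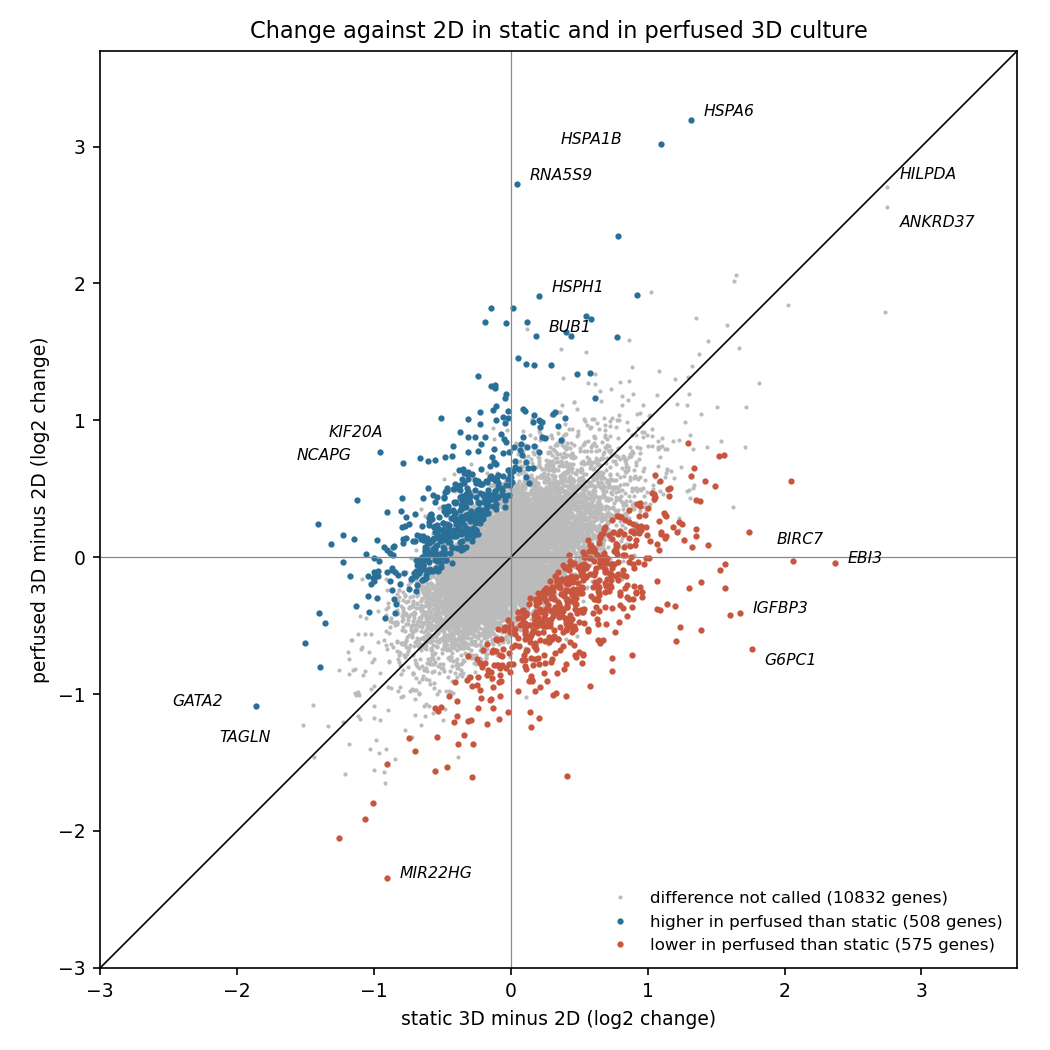
Log2 change against 2D of 11915 genes in static 3D (horizontal axis) and perfused 3D (vertical axis); the diagonal marks equal change, and colours mark the 508 genes higher and 575 lower in perfused than in static 3D. HILPDA and ANKRD37 lie near the diagonal, HSPA6, HSPA1B and RNA5S9 far above it, and EBI3 and BIRC7 far below it.

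Camera called several lists of liver function in no comparison. In static 3D against 2D, perfused 3D against 2D and perfused against static 3D, cytochrome P450 and phase I genes rose in 3, 5 and 2 and fell in 2, 3 and 6 of 29, phase II enzymes rose in 1, 1 and 2 and fell in 0, 2 and 0 of 24, and hepatic transporters rose in 4, 2 and 0 and fell in 3, 4 and 2 of 21. AOX1, an aldehyde oxidase, was at least 2.46-fold higher in static and at least 1.85-fold higher in perfused 3D than in 2D. Hepatocyte transcription factors rose in 4, 3 and 1 and fell in 2, 4 and 2 of 22, bile acid genes rose in 2, 1 and 1 and fell in 0 of 9, and fatty acid oxidation genes rose in 3, 0 and 1 and fell in 1, 0 and 3 of 30. Oxidative phosphorylation genes rose in 1, 2 and 1 and fell in 3, 0 and 0 of 47. Fry, added after seeing the data, called bile acid genes higher in static (adjusted p = 0.0180) and perfused 3D (adjusted p = 0.0262) against 2D. It called P450 and phase I genes higher in static 3D (adjusted p = 0.0275), although the median change of that list was -0.004 there. By fry, P450 and phase I genes and transporters were lower in perfused than in static 3D (adjusted p = 0.0393 each), with medians of -0.14 and -0.15. The reference genes, called by fry higher in static 3D (adjusted p = 0.00302) and lower in perfused than in static 3D (adjusted p = 0.00478), rose in 4, 1 and 0 and fell in 1, 1 and 1 of 14, while GAPDH changed by 0.15 ± 0.11 against 2D in both formats and was not called, except higher in static 3D with the authors' values (adjusted p = 0.0476). Of the markers of other cell types, 1 leukocyte gene rose and 1 fell of 9 in static 3D, 1 fell in each of the other two comparisons, 1 fibroblast gene of 5 fell in static 3D and 1 rose in perfused against static 3D, where fry called the fibroblast list higher (adjusted p = 0.0393), and 1 of 14 endothelial markers passed the detection filter and was not called.

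Nor did camera call the lists of unfolded protein response, p53, interferon, extracellular matrix, integrin, TGF-beta and Wnt genes in any comparison. Of these, fry called Wnt targets higher in static 3D (adjusted p = 0.00302) and lower in perfused than in static 3D (adjusted p = 0.0156), and integrin and junction genes higher in static 3D (adjusted p = 0.0196). In the same order of comparisons, unfolded protein response genes rose in 0, 0 and 3 and fell in 4, 2 and 3 of 23, p53 targets rose in 1, 2 and 3 and fell in 2, 1 and 1 of 21, and interferon-stimulated genes rose in 1, 0 and 0 and fell in 1 of 21 each time. Extracellular matrix genes rose in 3, 1 and 1 and fell in 0, 2 and 2 of 30, integrin and junction genes rose in 4, 3 and 1 and fell in 1, 1 and 3 of 26, TGF-beta and mesenchymal genes rose in 1, 4 and 1 and fell in 1, 0 and 1 of 16, and Wnt targets rose in 3, 1 and 1 and fell in 2, 1 and 3 of 16. CDH1 rose in static 3D against 2D 1.87-fold.

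Camera called other lists in some comparisons only, and the values in parentheses are its adjusted p where it did not, or that of limma for a single gene. In static 3D against 2D, heat shock genes rose in 1 and fell in 3 of 20 (adjusted p = 0.475), immediate early genes rose in 5 and fell in 4 of 20 (0.776), glycolysis genes rose in 1 and fell in 1 of 22 (0.14), amino acid degradation genes rose in 5 of 36 (0.243), and ATF4 genes rose in 4 and fell in 4 of 26 (0.776). In perfused 3D against 2D, cholesterol genes fell in 1 of 23 (0.640), fatty acid synthesis genes rose in 2 and fell in 1 of 25 (0.698), lysosomal genes rose in 2 and fell in 1 of 33 (0.426), NRF2 targets rose in 1 and fell in 4 of 24 (0.987), cytoskeletal genes rose in 1 and fell in 2 of 30 (0.354), and 0 of 16 NF-kappaB genes passed (0.114). Between the 3D formats, 0 of 12 histone genes passed (0.618), YAP and SRF targets rose in 2 and fell in 1 of 21 (0.823), metallothioneins rose in 1 of 8 (0.235), and oncofetal genes rose in 1 and fell in 2 of 19 (0.0691). Acute phase genes there rose in 2 and fell in 1 of 21 (0.503). Fry called the oncofetal (adjusted p = 0.0171) and lysosomal (adjusted p = 0.0393) lists lower and the cytoskeletal list higher (adjusted p = 0.0415) between the 3D formats. Of the genes given whatever their values, CYP1A1 changed by -0.13 in static 3D (0.765) and fell by 0.97 ± 0.25 between the 3D formats (0.0351), a call lost without any static array or perfused replicate 1 or 2 (adjusted p from 0.00712 to 0.123). HNF4A changed by -0.34 in static 3D (0.148) and 0.50 between the 3D formats (0.0629), where ALB changed by -0.02 and AFP and GAPDH by 0.00.

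Camera at its preset correlation called 11 lists higher and 7 lower in static 3D, 7 and 3 in perfused 3D, and 5 and 9 in perfused against static 3D, out of 40 each. With the estimated correlation camera called 0 in each comparison. The lowest adjusted p values were 0.0558 for ribosomal proteins in static 3D, 0.162 in perfused 3D and 0.0822 for mitosis genes in perfused against static 3D, and 5, 6 and 3 lists had an unadjusted p under 0.05. Fry called 21, 8 and 18 lists, of which 16, 7 and 10 were among those called by camera at its preset correlation. Of the lists camera called, fry did not call DNA replication (adjusted p = 0.0637) and cholesterol genes (adjusted p = 0.111) in static 3D. In perfused 3D it did not call DNA replication (adjusted p = 0.214), metallothionein and immediate early genes (adjusted p = 0.0627 each). Between the 3D formats it did not call cholesterol (adjusted p = 0.0513), amino acid degradation (adjusted p = 0.0787), hypoxia-responsive and glycolysis genes (adjusted p = 0.126 each). A change of at least 2-fold was reached by 130 higher and 60 lower genes in static 3D, 104 and 77 in perfused 3D, and 72 and 108 in perfused against static 3D.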

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

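Of all tested genes, 7 changed against 2D in opposite directions in static and perfused 3D, with the difference between the 3D formats also past the threshold. Of these, 3 belong to the cell cycle. NCAPG, of condensin, changed by -0.96 in static and 0.77 in perfused 3D, a difference of 1.73. The kinesin KIF20A changed by -0.66 and 0.73, a difference of 1.39, and MCM3, of the replicative helicase, by -0.40 and 0.40, a difference of 0.81. C20orf204 moved the same way, and CASTOR3P, DORIP1 and PIGZ the other way. Under median scaling none of the listed replication genes, MCM3 included, fell in static 3D. Among lists, G2/M and mitosis and DNA replication and G1/S were called lower in static and higher in perfused 3D against 2D, and the median change from static to perfused 3D was 0.81 and 0.57. Under median scaling camera still called both lower in static 3D, but their medians there were -0.029 and -0.085. For mitosis, adjusted p = 0.364 in static and adjusted p = 0.162 in perfused 3D with an estimated correlation, and for replication adjusted p = 0.441 and adjusted p = 0.739 with an estimated correlation. The replication call in perfused 3D was also lost without perfused replicate 3 (adjusted p = 0.192, with 1 gene rising and 2 falling). Of 625 passing probes with no gene symbol, 34 passed the threshold in static 3D against 2D, 20 in perfused 3D against 2D and 20 in perfused against static 3D. These were 5.44%, 3.2% and 3.2% of them, against 12%, 8.46% and 7.95% of the probes with a symbol.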

How the results depend on the processing

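Fry, median scaling for lists and the detection floor for partly detected genes were chosen only after the results were seen. The number of genes higher in static 3D was 1743 with median scaling and 1842 with the authors' values. It was 46 within BeadChip 1, 236 at an adjusted p under 0.01, 130 at 2-fold or more, and 341 to 1085 with 1 array left out. The number lower was 1143 without background correction, 159 with median scaling, 365 with the authors' values, 1163 with array weights, 13 within BeadChip 1, 187 at an adjusted p under 0.01, 60 at 2-fold or more and 285 to 997 with 1 array left out.

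In perfused 3D against 2D the higher genes numbered 844 without background correction, 1008 with median scaling, 1197 with the authors' values, 336 without the detection filter, 841 with a trend and robust variance, 339 with only those groups, 24 within BeadChip 1, 106 at an adjusted p under 0.01, 104 at 2-fold or more and 213 to 532 with 1 array left out. The lower genes numbered 940, 177, 365 and 387 with the first 4 of these, 369 with only those groups, 15 within BeadChip 1, 128 at an adjusted p under 0.01, 77 at 2-fold or more and 211 to 569 with 1 array left out.

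Between perfused and static 3D, the higher genes numbered 835 without background correction, 301 with median scaling, 792 with a trend and robust variance, 0 within BeadChip 1, 124 at an adjusted p under 0.01, 72 at 2-fold or more and 180 to 614 with 1 array left out. The lower genes numbered 874 with the authors' values, 0 within BeadChip 1, 150 at an adjusted p under 0.01, 108 at 2-fold or more and 245 to 633 with 1 array left out. A stricter threshold lowers counts by construction. For the other moves the cause was not tested.

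With the estimated correlation 0 lists were higher and 0 lower in each comparison, and the cause was not tested. In static 3D 7 to 11 lists were higher with 1 array left out. The correlation of the static and perfused changes was 0.452 to 0.593 with 1 array left out, for which no values without change were simulated. SALL4, called higher in static 3D, changed by -0.0194 within BeadChip 2, which holds 1 array per format. With replicate number as a block, as if the numbers paired the arrays, 701 genes were higher and 618 lower in static 3D, 419 and 457 in perfused 3D, and 405 and 466 in perfused against static 3D. Of 395 named results past the threshold, 200 stayed past it with any 1 array left out.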

Other observations

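Spliceosomal and other small structural RNAs were not described as a group above. RNA5S9, a 5S ribosomal RNA, rose in perfused 3D by 2.72 ± 0.31 against 2D and 2.68 ± 0.31 against static 3D. Of the 7 RNAs of its class (5S, 7SK, Y and related), 2 rose and 0 fell in perfused 3D against 2D, with a median of 0.40. The other that rose was RN7SK, by 1.06. Of 11 spliceosomal small nuclear RNAs, 6 rose and 0 fell in perfused 3D against 2D, with a median of 0.74, and 0 rose and 2 fell in static 3D. Of the 6, 5 were copies of U1 and the other was RNU6ATAC (0.74, adjusted p = 0.0484), a grouping made after the values were seen. Against static 3D the U6 genes RNU6-1 (0.87, adjusted p = 0.0132) and RNU6-15P (0.89, adjusted p = 0.00805) were higher in perfused 3D. But both had fallen in static 3D against 2D (-0.65 and -0.60) and were not called in perfused 3D against 2D (0.23 and 0.29). In the U1 copies perfused replicate 3 lay below the other perfused arrays, as in RNU1-3 at 10.2 against 11.9 and 12.4 log2 units, but in RNA5S9 it lay highest. RNU1-3 rose by 1.97 against static 3D, or 1.53 to 2.61 with 1 array left out, and the call was lost without static replicate 2 or 3 or perfused replicate 1 or 2 (adjusted p from 0.00314 to 0.0705). Many of these genes have near-identical copies that a probe may not separate.

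The tests of BeadChip, of cross-hybridization and of a single perfused array were chosen only after the results were seen. Perfused replicate 3 lay apart in the hypoxia list, by -0.647 from perfused replicate 1 on the same BeadChip, while BeadChips differed by at most 0.0996 within 2D and static 3D, so the BeadChip is an unlikely source. If a 2D or a static 3D sample had been mislabelled, the array should lie at that group, but it lay 0.695 of the way from 2D and 0.728 of the way from static 3D to the other perfused arrays. If that array came from a separate culture, a difference in oxygen supply or cell density could give lower hypoxia and higher replication genes. The data have no measure of either.

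For the heat shock genes, cross-hybridization between HSPA1A and HSPA1B is unlikely to be the whole source, as 11 of 18 other members were higher in perfused than in static 3D and 0 lower. Over 4 normalizations the list rose by at least 0.640 relative to all genes. The lowest perfused array lay 0.548 above the highest other array, so the rise did not rest on a single array. The labels do not say that the perfused arrays came from separate cultures, so this cannot tell whether a single culture gave the rise. The rise over static 3D may come from flow, from temperature in the bioreactor or from handling at harvest. These all went with perfusion and cannot be told apart here. For HSPA6 and HSPA1B the change was smaller against static 3D than against the monolayer. Part of their rise over the monolayer was therefore already present without perfusion.

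A higher yield of all small RNAs could raise the structural ones. But in perfused 3D against 2D the median change of 87 small nucleolar and Cajal body RNAs was -0.0337, with 3 rising and 7 falling. In static 3D against 2D their median was -0.240, with 1 rising and 14 falling. The rises from static to perfused 3D were not tested in this way, so a higher yield stays open for them. RNA isolation that differs by RNA class might still raise the structural RNAs, and was not tested.

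For chance, 10 splits of 6 arrays are too few for a share under 0.05. The real split called 1582, 1176 and 1083 genes, and it was the 1 of 10 splits that reached that number in each comparison. The highest other split called 0. Every other split mixes both formats in each group, which widens the spread within groups. Its count therefore does not show how many genes chance alone would call.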
